A study of Mus musculus with 3 samples.

How the data were processed

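Cells of mouse intervertebral discs at postnatal day 30, enriched by sorting for tdTomato in mice with Cre at the Shh locus, were profiled with the 10x Genomics Chromium Single Cell 3' kit v3. The 3 libraries are replicates of 1 group, each a pool of litter-matched animals. The labels state replicate sequencing batches, and whether libraries 2 and 3 shared a run is not given. The deposited matrices hold counts per gene and barcode, that is whole numbers of UMIs without normalization, on a filtered list of barcodes. The labels name Cell Ranger 3.0.2, Seurat 4 and mm10 without saying what each did, while the matrix header of library 1 names version 3.0.1 and those of libraries 2 and 3 name 6.0.0. Library 1 lists 31053 genes and libraries 2 and 3 list 32285. The 30406 Ensembl gene IDs shared by all 3 were used, which hold 99.9%, 99.6% and 99.6% of the UMIs of libraries 1, 2 and 3. Symbols were those of libraries 2 and 3, 597 shared IDs had another symbol in library 1, and 62 genes share a symbol with another gene and were told apart by ID. Gene positions came from the GENCODE vM21 annotation of mm10.

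Counts were read and cells handled in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5 with its Scrublet, igraph 0.11.9 and leidenalg 0.10.2. The filters, tests, gene lists, alternatives and the rule for named genes were set before the data were examined, except where said otherwise. Barcodes with at least 500 genes and at most 15% of UMIs from mitochondrial genes were kept, 5732, 10786 and 10364 in libraries 1, 2 and 3. The cells with the highest Scrublet scores were removed as doublets at a rate of 0.8% per 1000 barcodes, which took 7.71%, 10.3% and 9.40% of them. Counts scaled to 10000 per cell were log-transformed. The 2000 most variable genes within libraries, leaving out genes of the fixed lists, were centred and scaled within each library. Leiden clustering at resolution 0.8 used 30 principal components and 20 exact nearest neighbours. Clusters were named by 23 fixed marker lists, the nucleus pulposus by Krt8, Krt18, Krt19 and T as the series does. A check added after the data were seen asked for at least 3 of a class's markers in 10% of a library's cells of a named cluster and, for each nucleus pulposus-like cell, a UMI of at least 2 of the 4 markers.

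For each comparison, UMIs were summed per library and class and tested with edgeR 4.0.16 (quasi-likelihood test, filterByExpr, TMM) in R 4.3.3, with the library as replicate block because both sums of a library come from the same pool, as its number in the labels states. Adjusted p is by Benjamini-Hochberg over all genes tested, and a gene with adjusted p under 0.05 was called higher or lower. The quasi-likelihood test gives no SE. The SE printed with a log2 fold change is its absolute value over the square root of the test's F statistic. Comparisons were of nucleus pulposus-like cells with all other kept cells, with the chondrocyte-like, annulus or tendon fibroblast-like, osteoblast-like, bone marrow stromal-like and loose fibroblast-like cells together, and with each of these classes that had at least 20 cells in every library. The clusters and the tests use the same counts, so a gene that drives the clustering differs by construction, and counts are also given outside the genes used in clustering or naming. The named genes are the 12 largest and 12 smallest log2 fold changes among genes called, in the same direction in 3 of 3 libraries and with a mean of at least 50 CPM in the higher sum, and 2 members each way of every fixed list, of which 1 result is not reported here. For clusters they are the 5 largest and 3 smallest and 3 members of each list called. Naming, mitochondrial, ribosomal, haemoglobin, immunoglobulin and unnamed-model genes were left out of this rule, and the text prints part of the genes it gave. The naming genes were tracked beside them.

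The 24 gene lists were the notochord and nucleus pulposus program, cartilage-type matrix, small leucine-rich proteoglycans and microfibrils, fibrillar and type VI collagens, glycosaminoglycan synthesis, basement membrane and laminin receptors, epithelial keratins and junctions, glycolysis, hypoxia response, nuclear-encoded mitochondrial respiration, osmotic regulation and transport, lysosome with vacuole and caveola, hedgehog, BMP and TGF-beta, Wnt, axon guidance, matrix proteases and inhibitors, inflammatory mediators, unfolded protein response, immediate early and dissociation response, proliferation, proposed disc progenitor markers, hypertrophy and mineralization, and senescence. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, on log2 CPM with a prior count of 2. A fold against a group at 0 is a bound against 3 UMIs over that group.

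Alternatives were mitochondrial limits of 5% and 25%, minimums of 200 and 1000 genes, no doublet removal, each library clustered alone, list genes kept in clustering, resolutions of 0.4 and 1.5, no replicate block, DESeq2 1.42.0, DESeq2 size factors, no count filter, a filter of at least 10 CPM in 3 sums, count splitting, equal cell numbers and leaving out each replicate. Doublets by Scrublet's own threshold, nucleus pulposus-like cells defined by 3 of the 4 markers, the cluster with mitochondrial RNA alone, and the comparison of both nucleus pulposus-like clusters were chosen after the data were seen. Counts simulated at the same library sizes with genes changed by 2, 4, 8 and 16-fold were run through the same tests. Calls with the right sign covered 6%, 8%, 28% and 72% of changed genes against all other cells, 0%, 32%, 60% and 96% against connective-tissue cells, 0%, 2%, 50% and 86% against stromal-like cells and 16%, 82%, 88% and 74% between the clusters. Unchanged genes made up 3.39%, 7.84%, 0% and 2.26% of those calls. With Scrublet's threshold the shares against connective-tissue cells were 4%, 74%, 96% and 100%. Shares of cells carry 95% exact Clopper-Pearson intervals, which, like the bounds, cover counting error alone. Figures were drawn with matplotlib 3.10.9. The tdTomato and Cre transcripts are not among the genes listed and were not analysed here.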

Results

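Single-cell RNA sequencing counted transcripts in cells of the intervertebral disc from mice at postnatal day 30. The mice carried Cre recombinase at the Shh locus and a Cre-dependent tdTomato reporter, which marks cells that express Shh or descend from cells that did. Cells positive for tdTomato were enriched by sorting. The data form 1 group of 3 libraries, each from a separate pool of litter-matched animals, with replicate sequencing batches by the labels. A difference between libraries is therefore also a difference between pools and may be one between batches. Library 1 held 64695292 unique molecular identifiers (UMIs) on 7430 barcodes, library 2 held 145925353 on 11767, and library 3 held 137188648 on 11032. The median barcode had 4459.5, 7842 and 8013.5 UMIs in libraries 1, 2 and 3. After filters and removal of predicted doublets, 5290, 9678 and 9390 cells were kept.

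Most kept cells were of blood or bone marrow type. Neutrophil lineage-like cells made up 32.4% ± 3.61 of kept cells (mean ± SD, n = 3 libraries), B lineage-like cells 10.8% ± 5.03, macrophage or monocyte-like cells 7.79% ± 5.58 and erythroid-like cells 7.74% ± 4.86. Blood and marrow classes together reached 61.7% ± 10.1. Connective-tissue classes other than the nucleus pulposus reached 11.4% ± 7.84. Chondrocyte-like cells numbered 986, 91 and 0 in libraries 1, 2 and 3, and osteoblast-like cells 3, 164 and 553. Annulus or tendon fibroblast-like cells numbered 0, 228 and 88, bone marrow stromal-like cells 36, 47 and 151, and loose fibroblast-like cells 49, 2 and 0. These counts depend on doublet removal. With Scrublet's own score threshold, a setting chosen after the data were seen, chondrocyte-like cells numbered 1095, 410 and 75, osteoblast-like cells 15, 183 and 595 and loose fibroblast-like cells 64, 30 and 90. No cluster was then named annulus or tendon fibroblast-like, and a cluster of 0, 267 and 52 cells led by Cytl1, Serpina1b and Prg4 was named chondrocyte-like. Cells without a name made up 21.7% ± 5.08. Several unnamed clusters, with Fcrla, Il7r or Rag1 among their leading genes, scored highest for B lineage but did not meet the naming rule. Another had Mpo and Flt3 among its leading genes. The blood and marrow share above may therefore be too low. Class names rest on fixed marker genes, whose levels are therefore not results.

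**Figure D1:**
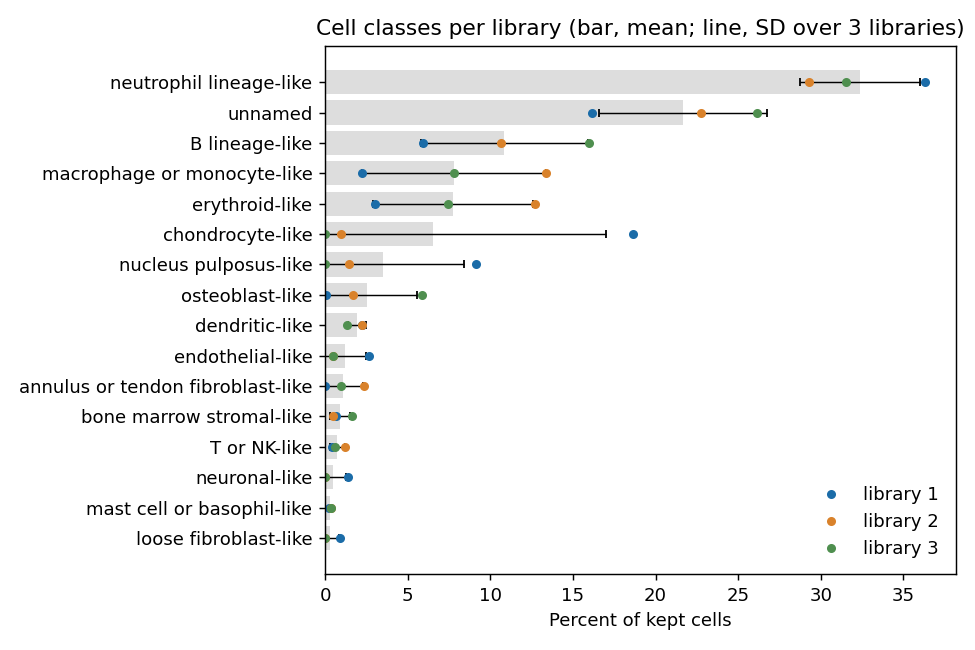
Percent of kept cells in each class, with 1 point per library, bars at the mean and lines at the SD over 3 libraries. Neutrophil lineage-like cells averaged 32.4%, and nucleus pulposus-like cells lay at 9.13%, 1.43% and 0.0213%.

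The series identifies nucleus pulposus cells within all sequenced cells by Krt8, Krt18, Krt19 and T, and the share of such cells was the first question. Nucleus pulposus-like (NP-like) cells numbered 483 in library 1, or 9.13% of kept cells (95% exact Clopper-Pearson interval 8.37 to 9.94). Library 2 had 138, or 1.43% (1.20 to 1.68). Library 3 had 2, or 0.0213% (0.00258 to 0.0769). The mean was 3.53% ± 4.90 (SD, n = 3), so the spread between libraries exceeded the mean. The preset doublet rate removed 24 of the 27 barcodes in library 3 that passed the cell filters with at least 3 of the 4 markers, where Scrublet's own score threshold removed 0. That threshold, chosen after the data were seen, gave 561, 169 and 27 NP-like cells. They made up 9.96%, 1.65% and 0.271% of kept cells, a mean of 3.96% ± 5.24. Counts of changed genes below are given with this threshold beside those of the preset rate. For gene lists, the calls it altered are given.

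The naming genes were measured in the 757 NP-like cells found with Scrublet's threshold, summed per library. The keratin gene Krt8 stood at 3206 ± 1255 CPM (UMIs of the gene scaled to a common total per sum), Krt18 at 992 ± 208, Krt19 at 2231 ± 230 and T, which encodes brachyury, at 975 ± 50.5 (SD, n = 3). At least 1 UMI was found in 97.9% ± 1.56 of these cells for Krt8, 79.8% ± 9.33 for Krt18, 99.3% ± 0.811 for Krt19 and 91.1% ± 4.17 for T. In B lineage-like cells, which should lack them, the shares were 1.02%, 1.30%, 1.18% and 0.278%, and in chondrocyte-like cells 1.75%, 1.06%, 1.87% and 0.995%. These 4 genes named the NP-like cells, each of which had to hold a UMI of at least 2 of them. The contrast is therefore set by the naming and is no test of it. Median UMIs per cell were 2796, 9692 and 2069 in the NP-like cells of libraries 1, 2 and 3 and 2863, 3364 and 2678.5 in B lineage-like cells. Shh, the gene whose locus drives Cre, was seen as 24 UMIs, at 3.28 ± 3.87 CPM and in 1.42% ± 1.28 of NP-like cells, against 0 UMIs in 2916 B lineage-like cells. Its share of NP-like cells was 2.50%, 1.78% and 0% in libraries 1, 2 and 3. Chondrocyte-like cells gave 13, 2 and 0 UMIs of Shh, in 1.19%, 0.488% and 0% of cells, at medians of 8961, 11657 and 10394 UMIs. On mouse build mm10, Krt8 (ENSMUSG00000049382) lies on chromosome 15 from 101996698 to 102004482 and Krt18 (ENSMUSG00000023043) from 102028180 to 102032027. Krt19 (ENSMUSG00000020911) lies on chromosome 11 from 100140810 to 100148665 and T (ENSMUSG00000062327) on chromosome 17 from 8434423 to 8442496.

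The next comparison asked what sets NP-like cells apart from all other kept cells. Sostdc1, which encodes a secreted antagonist of BMP and Wnt signals, stood at 809 ± 716 CPM in NP-like cells and 6.63 ± 11.1 in the others (SD, n = 3). Serpina1e, a serine protease inhibitor gene, stood at 2377 ± 1057 against 14.96 ± 24.2 CPM and the desmosomal gene Perp at 633 ± 201 against 4.58 ± 5.56. The muscarinic acetylcholine receptor gene Chrm2 stood at 242 ± 259 against 1.83 ± 2.97 CPM, the homeobox gene Barx2 at 297 ± 151 against 1.95 ± 2.92, and Cck, the cholecystokinin gene, at 750 ± 254 against 11.01 ± 17.3. Genes lower in NP-like cells included Cybb at 2.31 ± 4.002 against 461 ± 106 CPM and Pglyrp1 at 6.26 ± 7.03 against 1009 ± 229. Cybb was among the genes used in clustering. CPM values of the comparisons are TMM-scaled. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change was 10.68 (SE 1.44, adjusted p = 3.13e-11) for Sostdc1. It was 10.40 (SE 1.46, adjusted p = 1.97e-10) for Serpina1e and 7.90 (SE 1.04, adjusted p = 8.44e-12) for Perp. Each was higher in 3 of 3 libraries, although library 3 gave only 2 NP-like cells with 10859 UMIs. Without library 1, 2 and 3 in turn these became 12.26, 7.98 and 7.96 for Sostdc1, 11.84, 9.20 and 8.14 for Serpina1e, and 8.49, 7.30 and 7.52 for Perp. Sostdc1 (ENSMUSG00000036169) lies on chromosome 12 from 36314139 to 36318452, Serpina1e (ENSMUSG00000072849) on chromosome 12 from 103946931 to 103958975 and Perp (ENSMUSG00000019851) on chromosome 10 from 18845020 to 18857073.

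Of 13948 genes tested against all other cells, 3887 changed, 1385 higher and 2502 lower in NP-like cells. With DESeq2 size factors 1047 were higher and 3086 lower, and the median of all genes moved from -0.35 to -0.70 on the log2 scale. Under Scrublet's threshold 5529 of 14444 genes changed. In that set 1334 of the 1385 higher and 2271 of the 2502 lower genes were called in the same direction. Outside the genes used in clustering or naming, 2748 of 11904 changed. The other cells included 74 in a neuronal-like cluster, all of library 1, of which 59 were NP-like with Scrublet's threshold. NP-like cells formed 2 clusters with that threshold, described below, of which 1 was poor in mitochondrial RNA. In library 1, 481 of the 489 cells of the poor cluster were NP-like with the preset rate too. Most of the 59 therefore lay in the other cluster, which held 72 cells of library 1. The 483 NP-like cells of library 1 used here included 481 of the poor cluster. The levels given for the other cells therefore hold some NP-like transcripts. Among the 32 genes tracked here, Cd44 lost its call without library 1 (log2 fold change -1.93) and without library 2 (-2.44), and Spp1 without library 1 (3.06), 2 (2.17) or 3 (3.08). Acan lost it without library 2 (3.43) or 3 (1.83), and Rab38 (4.55) and Htra1 (4.32) without library 2. Shh and Dsg2 were not tested without library 1. The fold change of 20, 21 and 13 genes that kept their call moved by more than 1.5 times without library 1, 2 and 3, all in the same direction as before.

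Camera called 9 of 24 lists against all other cells, each with adjusted p = 0.932 with an estimated correlation. Of 13 epithelial keratin and junction genes, 7 were higher and 1 lower (camera adjusted p = 0.00256). Among them was Dsg2, a desmosomal cadherin gene, at 29.7 ± 32.8 against 0.186 ± 0.268 CPM. Glycolysis genes had 4 of 18 higher and 0 lower, with Aldoc at 81.0 ± 20.7 against 3.99 ± 2.93 CPM (adjusted p = 1.95e-05). Hypoxia-response genes had 8 of 18 higher and 0 lower, with the mitophagy gene Bnip3 at 645 ± 232 against 30.1 ± 24.4 (adjusted p = 4.68e-04). The notochord and nucleus pulposus program had 6 of 16 higher and 4 lower (adjusted p = 4.68e-04). The carbonic anhydrase gene Car3 stood at 18760 ± 11730 against 167 ± 81.2 CPM and Shh at 2.25 ± 1.95 against 0.183 ± 0.307. Basement membrane genes had 6 of 19 higher and 1 lower (adjusted p = 0.0145). Lysosome, vacuole and caveola genes had 5 of 23 higher and 2 lower (adjusted p = 0.0221), with Cav1, the main caveolar coat gene, at 687 ± 325 against 15.7 ± 22.1 CPM. The median of the lysosome list was 0.10 with TMM and -0.24 with DESeq2 size factors. Of 18 proliferation genes 17 were lower and 0 higher, including Ccna2 at 1.96 ± 1.73 against 126 ± 41.4 CPM (adjusted p = 4.68e-04). Of 16 proposed disc progenitor markers 9 were lower and 0 higher (adjusted p = 0.00261). Ctsk of this list is also an osteoclast marker used in naming. Since most other cells were of blood or marrow type, the proliferation and progenitor calls do not set NP-like cells against other disc cells alone. Of 11 inflammatory genes 6 were lower and 1 higher (adjusted p = 0.0221), with the chemokine gene Cxcl2 at 5.46 ± 8.07 against 371 ± 396 CPM. With an estimated correlation 0 of 24 lists had an unadjusted p under 0.05, and fry called 0 lists and had 2. Under Scrublet's threshold the inflammatory call was lost (adjusted p = 0.237) and glycosaminoglycan synthesis genes were called up (adjusted p = 0.0217, and adjusted p = 0.712 with an estimated correlation). The other 8 calls were kept there at the preset correlation, and 0 lists were called with an estimated correlation. Of the NP-like cells of the preset rate, 481 of 483 in library 1 and 38 of 138 in library 2 lay in a cluster poor in mitochondrial RNA, described below. As shares of UMIs, more glycolysis genes were higher than lower there, compared with the other NP-like cluster. The basement membrane genes and the 3 progenitor genes tested were lower. These list calls between the clusters were lost with an estimated correlation. With the other cluster alone, from Scrublet's threshold, the same 8 calls were kept and the same 1 was lost (adjusted p = 0.259) at the preset correlation, and 0 lists were called with an estimated correlation. The list medians were 0.81 there and 0.87 with the preset rate for glycolysis, 1.71 and 0.93 for basement membrane and -1.72 and -2.66 for progenitor markers. Adjusted over the list alone, the higher and lower counts were 7 and 1 for epithelial, 5 and 2 for glycolysis, 9 and 0 for hypoxia and 9 and 4 for the notochord program. They were 6 and 1 for basement membrane, 5 and 2 for lysosome, 0 and 17 for proliferation, 0 and 11 for progenitor and 1 and 7 for inflammatory genes.

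Because blood cells dominate the other cells, NP-like cells were next compared with neighbouring connective-tissue classes together. The make-up of this group differed between libraries. Chondrocyte-like cells were 986 of its 1074 cells in library 1, and osteoblast-like cells 553 of 792 in library 3. Each library therefore sets NP-like cells against another mix of classes, which the replicate block does not remove. Several of the largest rises were in genes named above. Sostdc1 stood at 815 ± 721 CPM against 0.949 ± 1.14, Serpina1e at 2394 ± 1064 against 13.1 ± 11.8, and Perp at 637 ± 202 against 2.17 ± 2.04 (SD, n = 3). Chrm2 stood at 244 ± 261 against 0.282 ± 0.247, and the surface protein gene Plet1 at 291 ± 138 against 1.78 ± 2.34. Cdh6, a cadherin gene, stood at 80.8 ± 86.0 against 0.178 ± 0.0239 CPM, and Hopx, a transcriptional cofactor gene used in clustering, at 1643 ± 110 against 5.06 ± 2.31. At the other end, Cilp2, a cartilage matrix gene, stood at 1.73 ± 2.32 CPM in NP-like cells against 698 ± 574, and Prg4, which encodes lubricin, at 1.13 ± 0.983 against 388 ± 284. The sphingomyelinase gene Smpd3 stood at 2.30 ± 2.68 against 661 ± 485 CPM and Igfbp5, which encodes an IGF-binding protein, at 1.13 ± 0.983 against 337 ± 81.0. Genes with 0 UMIs in NP-like cells give bounds against a floor of 3 UMIs over the group. These bounds cover counting error in the cells of the preset rate alone. The Wnt-inactivating gene Notum was at least 76.3-fold lower, Col8a1 at least 56.9-fold, Aspn at least 55.1-fold and Sod3 at least 40.2-fold. Under Scrublet's threshold, where library 3 gave more NP-like cells, the log2 fold change of Lox, a collagen cross-linking gene used in clustering with 0 UMIs in the preset set, was -6.88, of Notum -6.96, of Col8a1 -6.25 and of Sod3 -6.16.

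**Figure D2:**
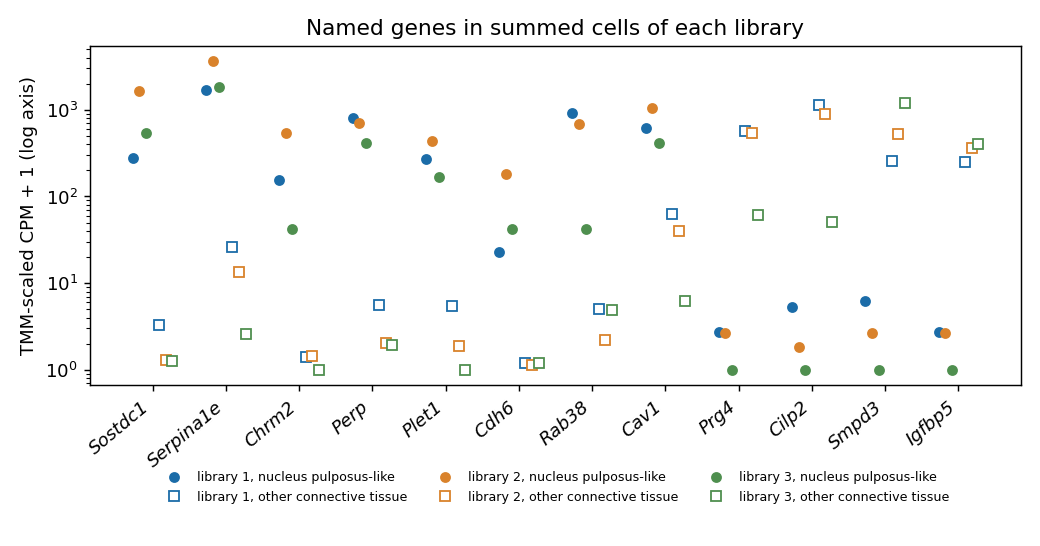
TMM-scaled CPM plus 1 on a log axis for 12 genes in the summed cells of each library, with filled circles for NP-like cells and open squares for other connective-tissue cells. Sostdc1 averaged 815 CPM against 0.949, and Prg4 averaged 1.13 CPM against 388.

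By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change against connective-tissue cells was 9.77 for Sostdc1 (SE 1.22, adjusted p = 4.12e-13). It was 8.48 for Perp (SE 1.08, adjusted p = 1.74e-12) and -8.23 for Prg4 (SE 1.28, adjusted p = 1.07e-08), each in the same direction in 3 of 3 libraries. The NP-like sum of library 3 held 10859 UMIs from 2 cells. A gene as low as Prg4 in NP-like cells would be expected at 0 UMIs there, so its direction in that library tells little. Without library 1, 2 and 3 these became 11.70, 8.62 and 9.16 for Sostdc1, 9.23, 8.06 and 8.39 for Perp, and -8.23, -8.21 and -8.22 for Prg4. In all, 1822 of 11095 genes changed, 549 higher and 1273 lower, and 1378 of 9662 outside the genes used in clustering or naming. With DESeq2 size factors 466 were higher and 1769 lower, and the median of all genes moved from -0.22 to -0.46. Scrublet's threshold gave 3368 of 12231 genes changed. Of the 549 higher genes 478, and of the 1273 lower genes 1170, were called in the same direction there. Of the 54 genes tracked here, 3 lost their call without library 1, 16 without library 2 and 1 without library 3. A further 28, 18 and 10 moved by more than 1.5 times in fold without a change of direction. On mm10, Prg4 (ENSMUSG00000006014) lies on chromosome 1 from 150449412 to 150466165 and Cilp2 (ENSMUSG00000044006) on chromosome 8 from 69880369 to 69887687.

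Camera called 17 of 24 lists against other connective-tissue cells, and 0 with an estimated correlation. Of 13 cartilage-type matrix genes, 9 were lower and 0 higher (10 lower adjusted over the list alone), and camera gave adjusted p = 4.81e-06 for the list and adjusted p = 0.484 with an estimated correlation. Small leucine-rich proteoglycan and microfibril genes had 14 of 17 lower and 0 higher (14 adjusted over the list alone; adjusted p = 7.50e-09, and adjusted p = 0.484 with an estimated correlation), where the microfibril gene Mfap4 was at least 70.2-fold lower and Ogn, the osteoglycin gene, at 14.8 ± 17.4 against 181 ± 78.4 CPM. Fibrillar and type VI collagen genes had 7 of 11 lower and 0 higher (7 adjusted over the list alone; adjusted p = 0.00118, and adjusted p = 0.484 with an estimated correlation). Col5a1 stood at 19.1 ± 28.0 against 571 ± 355 CPM and Col14a1 was at least 68.4-fold lower. Matrix protease and inhibitor genes had 13 of 20 lower and 0 higher (15 lower and 1 higher adjusted over the list alone; adjusted p = 8.37e-05, and adjusted p = 0.578 with an estimated correlation). Mmp2, a gelatinase gene seen as 1 UMI in NP-like cells, was lower by a ratio of 687 in the UMIs of all libraries together (counting interval 123 to 27149). The log2 fold change of Mmp2 was -8.551 in the edgeR fit and -7.415 with Scrublet's threshold, both smaller changes. The aggrecanase gene Adamts5 stood at 4.72 ± 6.72 against 40.5 ± 13.7 CPM. Hypertrophy and mineralization genes had 9 of 12 lower and 0 higher (9 adjusted over the list alone; adjusted p = 2.50e-06, and adjusted p = 0.527 with an estimated correlation). Glycosaminoglycan synthesis genes had 8 of 22 lower and 1 higher, with Chst15 at 1.39 ± 1.71 against 23.8 ± 6.51 CPM and Csgalnact1 higher at 172 ± 146 against 30.0 ± 30.3. The list was not called (9 lower and 1 higher adjusted over the list alone; adjusted p = 0.419). Basement membrane genes had 5 of 17 lower and 2 higher, with Col4a2 at 2.50 ± 3.60 against 52.0 ± 20.7 CPM and the laminin receptor gene Bcam higher at 27.8 ± 35.5 against 4.70 ± 2.63, again without a call (7 and 2 adjusted over the list alone; adjusted p = 0.682). Ogn lost its own call without library 2 (log2 fold change -4.64), as did Csgalnact1 (2.00). Of the NP-like cells of the preset rate, 481 of 483 in library 1 and 38 of 138 in library 2 lay in a cluster poor in mitochondrial RNA, described below, in which matrix transcripts were lower than in the other NP-like cluster. The median log2 fold change of the cartilage-type list was -5.80, against -4.21 with Scrublet's threshold and -3.53 in that set with the other NP-like cluster alone. The medians were -4.57, -4.74 and -3.94 for small leucine-rich proteoglycans, -4.50, -3.55 and -2.81 for collagens, -2.64, -2.55 and -1.95 for proteases and -4.72, -3.74 and -3.28 for hypertrophy. Those 5 calls were kept in both settings at the preset correlation, with adjusted p = 0.0181 for collagens with the other cluster alone, and 0 lists were called in either with an estimated correlation.

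Compared with other connective-tissue cells, genes of the hedgehog, BMP, TGF-beta and Wnt pathways were more often lower than higher. Hedgehog pathway genes had 7 of 11 lower and 1 higher (the same adjusted over the list alone; camera adjusted p = 0.00125, and adjusted p = 0.578 with an estimated correlation). Gli2, a transcription factor of the pathway, was at least 13.5-fold lower, while Disp1, needed for release of hedgehog ligand, was higher at 109 ± 95.1 against 12.2 ± 4.92 CPM. BMP and TGF-beta genes had 12 of 24 lower and 1 higher (13 and 1 adjusted over the list alone; adjusted p = 5.43e-04, and adjusted p = 0.527 with an estimated correlation), with the BMP antagonist gene Chrdl1 at least 24.2-fold lower and Tgfb2 higher at 182 ± 237 against 16.6 ± 12.98 CPM. Wnt genes had 12 of 16 lower and 0 higher (14 adjusted over the list alone; adjusted p = 1.77e-08, and adjusted p = 0.484 with an estimated correlation), with the R-spondin receptor gene Lgr6 at 0 UMIs (log2 fold change -4.95 with Scrublet's threshold) and Dkk3 at 2.25 ± 2.09 against 19.5 ± 8.10 CPM. The median of the Wnt list was -5.81, or -2.92 with its 7 genes at 0 set at their bounds. Axon guidance genes had 6 of 14 lower and 0 higher (the same adjusted over the list alone; adjusted p = 0.0764), among them Sema4d at 0 UMIs (log2 fold change -3.44 with Scrublet's threshold), and with Scrublet's threshold were called at the preset correlation (adjusted p = 0.0368) and not with an estimated correlation (adjusted p = 0.594). Proposed disc progenitor markers had 7 of 10 lower and 0 higher (the same adjusted over the list alone; adjusted p = 0.00196, and adjusted p = 0.578 with an estimated correlation). The TGF-beta co-receptor gene Eng stood at 2.25 ± 2.09 against 19.8 ± 1.63 CPM. The list medians were -2.26 with the preset rate, -2.24 with Scrublet's threshold and -1.65 with the NP-like cluster richer in mitochondrial RNA alone for hedgehog, -2.43, -1.95 and -1.50 for BMP and TGF-beta, -5.81, -3.20 and -2.48 for Wnt and -2.87, -2.28 and -1.78 for progenitor markers, of which 1 was higher in the last. These 4 calls were kept in both settings at the preset correlation, and 0 lists were called in either with an estimated correlation. Without library 2 the calls of Disp1 (log2 fold change 3.06) and Tgfb2 (2.41) were lost, and that of Tgfb2 also without library 3 (0.81).

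Glycolysis, hypoxia and lysosome lists had more genes higher than lower, and osmotic genes the reverse. Glycolysis genes had 4 of 18 higher and 0 lower than in other connective-tissue cells (5 higher adjusted over the list alone; camera adjusted p = 6.45e-08, and adjusted p = 0.484 with an estimated correlation). Aldoc stood at 81.6 ± 20.9 against 12.5 ± 11.8 CPM and the phosphofructokinase gene Pfkl at 321 ± 146 against 75.3 ± 48.4. Hypoxia-response genes had 3 of 18 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.0225, and adjusted p = 0.578 with an estimated correlation). Bnip3 stood at 650 ± 234 against 130 ± 96.9 CPM and the collagen prolyl hydroxylase gene P4ha2 lower at 40.8 ± 24.0 against 275 ± 63.1. Lysosome, vacuole and caveola genes had 4 of 21 higher and 0 lower (the same adjusted over the list alone; adjusted p = 0.00863, and adjusted p = 0.578 with an estimated correlation). Rab38, a GTPase gene of lysosome-related organelles, stood at 547 ± 453 against 3.06 ± 1.60 CPM and Cav1 at 692 ± 327 against 35.3 ± 28.4. The median of this list was 0.04 with TMM and -0.12 with DESeq2 size factors. Of these NP-like cells, 481 of 483 in library 1 and 38 of 138 in library 2 lay in the cluster poor in mitochondrial RNA. At an unadjusted p under 0.05 by edgeR, glycolysis had 5 genes higher and 0 lower. With Scrublet's threshold these were 10 and 1, and with the other NP-like cluster alone 11 and 0. Hypoxia had 7 and 1, 7 and 4, and 8 and 2 in that order. The lysosome list had 4 and 1, 9 and 4, and 9 and 1. None of 28 nuclear genes of mitochondrial respiration passed, over all genes or adjusted over the list alone, and edgeR gave 0 at an unadjusted p under 0.05 (camera up, adjusted p = 0.0175, and adjusted p = 0.714 with an estimated correlation), while the list median of -0.14 and mean of -0.11 were below 0. That call was lost with Scrublet's threshold (adjusted p = 0.389) and with the NP-like cluster richer in mitochondrial RNA alone (adjusted p = 0.781). Osmotic and ion transport genes had 6 of 14 lower and 1 higher (7 and 1 adjusted over the list alone; adjusted p = 0.378), with the inositol transporter gene Slc5a3 at 2.77 ± 4.07 against 43.7 ± 34.7 CPM and the sodium-potassium-chloride cotransporter gene Slc12a2 higher at 694 ± 787 against 30.2 ± 11.3. Without library 2 the calls of Aldoc (log2 fold change 3.12), Pfkl (2.33), Bnip3 (3.25), P4ha2 (-3.58) and Slc12a2 (2.92) were lost, and without library 1 that of P4ha2 (-2.15).

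The 6 epithelial keratin and junction genes tested had 2 higher and 0 lower, with Perp among the higher against connective-tissue cells (the same adjusted over the list alone; camera up, adjusted p = 0.130, median -0.18, mean 1.31). With Scrublet's threshold the list had 5 of 10 higher and 2 lower and was called up at the preset correlation (adjusted p = 0.00269) and not with an estimated correlation (adjusted p = 0.4135). The notochord and nucleus pulposus program had 4 of 14 higher and 4 lower (the same adjusted over the list alone; camera up, adjusted p = 0.0920, median -0.37, mean -1.42), with Car3 at 18890 ± 11810 against 950 ± 884 CPM, the galectin gene Lgals3 at 8784 ± 2715 against 416 ± 341, and the BMP antagonist gene Nog at 0 UMIs (log2 fold change -3.73 with Scrublet's threshold). Unfolded protein response genes had 4 of 17 lower and 0 higher (the same adjusted over the list alone; adjusted p = 0.0115), with the chaperone gene Hspa5 at 125 ± 57.4 against 727 ± 215 CPM. Under Scrublet's threshold 15 of 17 were lower (adjusted p = 4.78e-04, and adjusted p = 0.4135 with an estimated correlation), and with the NP-like cluster richer in mitochondrial RNA alone 6 of 17 (adjusted p = 0.00639, and adjusted p = 0.468 with an estimated correlation). The list median was -1.72 with the preset rate, -1.23 with that threshold and -0.80 with that cluster alone. Immediate early genes had 4 of 18 lower and 1 higher (12 and 1 adjusted over the list alone; adjusted p = 0.0262), with Socs3 at 50.8 ± 72.7 against 366 ± 275 CPM and the small heat shock gene Hspb1 higher at 1692 ± 1092 against 67.9 ± 55.1. Proliferation genes had 4 of 18 lower and 0 higher (the same adjusted over the list alone; adjusted p = 0.0384), with the kinetochore gene Cenpf at 6.17 ± 6.21 against 39.0 ± 11.5 CPM. Senescence genes had 3 of 10 lower and 0 higher (4 adjusted over the list alone; adjusted p = 0.0175) and inflammatory genes 3 of 7 lower and 0 higher (the same adjusted over the list alone; adjusted p = 0.0860), with the growth factor gene Csf1 at 1.41 ± 1.27 against 35.6 ± 19.3 CPM. The unfolded protein response, immediate early and senescence calls had adjusted p = 0.578 with an estimated correlation and the proliferation call adjusted p = 0.614 with an estimated correlation. The immediate early and senescence calls were lost with Scrublet's threshold (adjusted p = 0.220 and 0.787) and with the NP-like cluster richer in mitochondrial RNA alone (adjusted p = 0.781 and 0.961), where the immediate early list had 1 gene lower and 1 higher. Proliferation was called with Scrublet's threshold (adjusted p = 0.0421, and adjusted p = 0.594 with an estimated correlation) and not with that cluster alone (adjusted p = 0.0515). Over all 24 lists, camera with an estimated correlation called 0 and had 1 at an unadjusted p under 0.05, and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 0 and had 9. Fry's mixed test, which asks for changes in either direction, called 11. Under Scrublet's threshold fry called 11 and its mixed test 20. Without library 2 the calls of Car3 (log2 fold change 5.01), Lgals3 (5.60), Hspa5 (-2.95), Socs3 (-4.84), Hspb1 (5.34), Csf1 (-3.38) and Cenpf (-2.99) were lost. Hspa5 (-1.92) and Socs3 (-1.92) also lost theirs without library 1.

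Bone marrow stromal-like cells were the only other connective-tissue class with at least 20 cells in every library and were compared alone. Serpina1e stood at 3147 ± 1327 CPM in NP-like cells and at 0 in stromal-like cells (log2 fold change 10.19 with Scrublet's threshold). Sostdc1 stood at 1068 ± 918 CPM and was at least 574-fold higher, and Perp and Plet1 at least 442-fold and 211-fold (SD, n = 3; floor of 3 UMIs over the group). The aggrecan gene Acan stood at 5738 ± 4940 against 7.93 ± 9.61 CPM, the hyaluronan link protein gene Hapln1 at 830 ± 808 against 4.18 ± 4.73, and Fmod, which encodes fibromodulin, at 1309 ± 570 against 24.5 ± 13.1. Lower in NP-like cells were Igfbp5 at 1.46 ± 1.27 against 1572 ± 857 CPM, the osteogenic transcription factor gene Runx2 at 2.19 ± 1.90 against 384 ± 63.1, and Csf1 at 1.82 ± 1.64 against 318 ± 40.2. The semaphorin receptor gene Nrp1 stood at 1.44 ± 1.62 against 207 ± 50.2 CPM, and Fbln5 was at least 368-fold lower. Rspo3 and Col8a1 had 0 UMIs in NP-like cells, with log2 fold changes of -6.78 and -7.72 with Scrublet's threshold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold change was 7.17 for Hapln1 (SE 1.25, adjusted p = 2.76e-07) and -6.86 for Runx2 (SE 1.16, adjusted p = 1.31e-07), in the same direction in 3 of 3 libraries. In library 3, with 2 NP-like cells and 10859 UMIs, a gene as low as Runx2 would be expected at 0 UMIs, so its direction there tells little. Without library 1, 2 and 3 these were 8.13, 5.83 and 7.86 for Hapln1 and -6.70, -7.10 and -6.85 for Runx2. In all 1414 of 7844 genes changed, 365 higher and 1049 lower, and 978 of 6791 outside the genes used in clustering or naming. The count fell to 722 without library 1 and 413 without library 2 and was 1914 without library 3. With DESeq2 size factors 353 were higher and 1840 lower, and the median of all genes moved from -0.19 to -0.67. Scrublet's threshold gave 3213 of 9820. Of the 29 genes tracked here, Lgals3 lost its call without library 1 (8.55) or 2 (9.28), and Acan (6.94), Fmod (4.82), Bnip3 (5.84), Chrdl1 (-8.15), Col4a1 (-5.03), Serpine2 (-9.54) and Nt5e (-3.05) without library 2. The fold of 7 that kept their call moved by more than 1.5 times without library 1, of 7 without library 2 and of 7 without library 3.

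Against stromal-like cells, 11 of 15 glycolysis genes were higher and 0 lower (12 adjusted over the list alone; camera adjusted p = 1.14e-13), with Aldoc at 108 ± 27.4 CPM and at least 47.8-fold higher. The notochord program had 5 of 7 higher and 0 lower (adjusted p = 3.22e-06), with Lgals3 at 11520 ± 3195 against 30.7 ± 23.8 CPM. Cartilage-type matrix genes had 4 of 8 higher and 0 lower (adjusted p = 6.23e-04). Against all connective-tissue cells most members tested were lower, but more members were tested there, and the comparisons were not tested against each other. Hypoxia-response genes had 3 of 13 higher and 1 lower (adjusted p = 6.23e-04), with Bnip3 at 852 ± 282 against 11.6 ± 2.19 CPM. Lysosome genes had 3 of 20 higher and 0 lower (adjusted p = 0.0422), with Cav2 at 365 ± 124 against 3.07 ± 3.77. Lower lists were matrix proteases with 13 of 17 lower and 1 higher (adjusted p = 9.43e-05), Wnt with 7 of 9 and 0 (adjusted p = 9.77e-05), and hypertrophy with 9 of 12 and 1 (adjusted p = 6.23e-04). Also lower were small leucine-rich proteoglycans with 9 of 12 and 2 (adjusted p = 0.0074), hedgehog with 7 of 10 and 1 (adjusted p = 0.0152) and basement membrane with 6 of 12 and 0 (adjusted p = 0.0152). BMP and TGF-beta genes had 10 of 17 lower and 2 higher (adjusted p = 0.001985), proposed progenitor markers 6 of 9 and 0 (adjusted p = 0.0165) and inflammatory genes 2 of 4 and 0 (adjusted p = 0.0218). Nuclear genes of respiration were called up (adjusted p = 0.00966), though 0 of 28 passed and edgeR gave 0 at an unadjusted p under 0.05. Adjusted over the list alone, hypoxia had 4 higher and 1 lower, matrix proteases 13 lower and 2 higher, Wnt 8 and 0, basement membrane 7 and 1 and BMP 11 and 2, and the other lists named had the same counts. Each call of this comparison was lost with an estimated correlation, with adjusted p = 0.605 or above with an estimated correlation. Camera so run called 0 lists and had 0 at an unadjusted p under 0.05, and fry called 0 and had 12. Most NP-like cells of library 1 in this comparison, 481 of 483, and 38 of 138 in library 2 lay in the cluster poor in mitochondrial RNA described below. As shares of UMIs, matrix, basement membrane and most protease genes tested were lower there than in the other NP-like cluster. More glycolysis genes were higher than lower. These list calls between the clusters were lost with an estimated correlation. With Scrublet's threshold the basement membrane (adjusted p = 0.574), respiration (0.0768), hedgehog (0.130), inflammatory (0.217) and progenitor (0.0501) calls were lost and immediate early genes were called up (0.00298). With the other NP-like cluster alone these 5 calls were also lost, as were those of small leucine-rich proteoglycans (adjusted p = 0.0811) and BMP and TGF-beta genes (0.193), while immediate early (4.45e-04) and glycosaminoglycan synthesis genes (0.00868) were called up. The other 8 calls were kept in both settings at the preset correlation, and 0 lists were called in either setting with an estimated correlation. With that cluster alone the list medians were 2.63 for glycolysis, against 3.28 with the preset rate, -3.73 for proteases, against -4.72, and -0.40 for basement membrane, against -2.10.

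NP-like cells formed 2 clusters that differed in mitochondrial and nuclear RNA. In the set from Scrublet's threshold, 489, 38 and 20 cells of libraries 1, 2 and 3 lay in a cluster with a median of 0.0544%, 0.0268% and 0.0568% of UMIs from mitochondrial genes. The other cluster held 72, 131 and 7 cells with 2.87%, 3.08% and 2.11%. Median UMIs per cell were 2429, 2983.5 and 1587.5 in the first and 13598.5, 10813 and 4714 in the second. Malat1, a nuclear long noncoding RNA, gave 5.44, 1.60 and 37.1 UMIs per 10000 in the first and 217, 265 and 397 in the second. With each cell thinned to 1000 UMIs, a Malat1 UMI was found in 16.8% (95% exact Clopper-Pearson interval 13.5 to 20.5), 21.1% (9.55 to 37.3) and 33.3% (13.3 to 59.0) of the first. It was found in 100%, 99.2% and 100% of the second and in 98.3%, 99.0% and 98.6% of B lineage-like cells. Ribosomal protein genes gave 32.3%, 32.8% and 27.9% of UMIs in the first and 18.8%, 18.2% and 14.8% in the second.

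**Figure D3:**
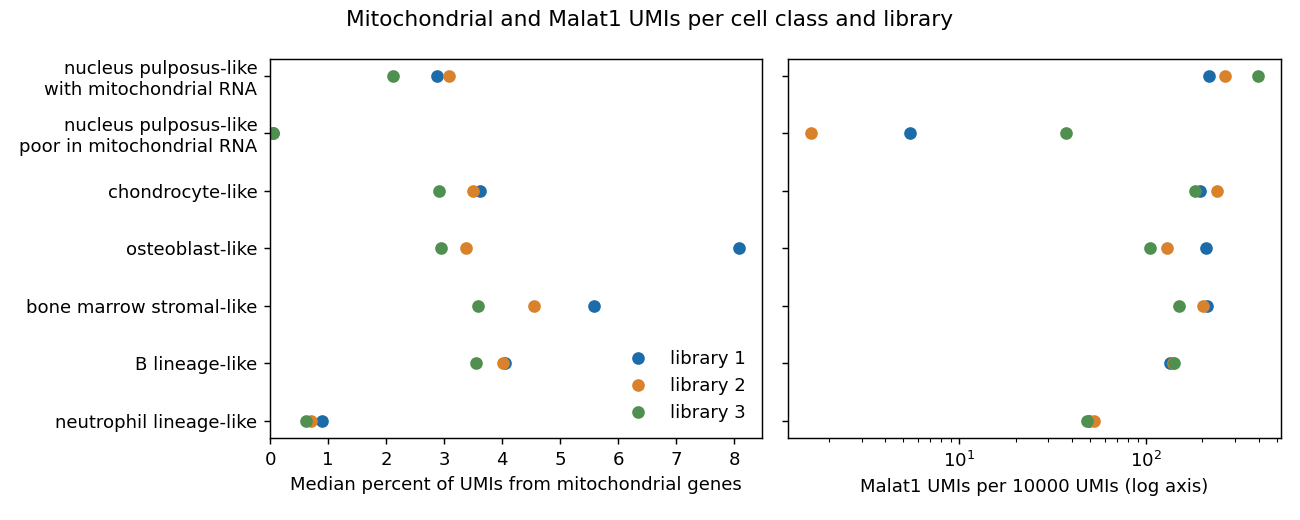
Median percent of UMIs from mitochondrial genes (left) and Malat1 UMIs per 10000 UMIs on a log axis (right) in each cell class, with 1 point per library. The cluster poor in mitochondrial RNA lay between 0.0268% and 0.0568%, and the other NP-like cluster between 2.11% and 3.08%.

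The planned comparison of NP-like sub-clusters needed 20 cells per cluster and library and could not be run with 2 NP-like cells in library 3. The 2 clusters above were compared instead, a choice made after the data were seen. The cluster with mitochondrial RNA had more transcript of the matrix genes Col2a1 at 3557 ± 2681 against 59.1 ± 64.1 CPM, Acan at 6372 ± 2071 against 187 ± 78.5 and Col11a1 at 616 ± 408 against 19.0 ± 10.4 (SD, n = 3). Malat1 stood at 27570 ± 2992 against 1271 ± 1485. Myl7, a myosin light chain gene, was lower at 34.3 ± 13.4 against 206 ± 88.8 CPM. Of the naming genes, Krt8 stood at 2677 ± 789 against 3622 ± 459 CPM and Krt19 at 1901 ± 669 against 2865 ± 1075. Krt18 at 932 ± 288 against 1076 ± 300 and T at 878 ± 271 against 1007 ± 261 did not pass (adjusted p = 0.201 and 0.405). CPM are shares of UMIs, and cells of the cluster with mitochondrial RNA held more UMIs. In library 1, Krt8 gave 1801 UMIs in the 72 cells of that cluster and 3824 in the 489 cells of the other. For Krt8 the lower CPM was therefore not fewer UMIs per cell there. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold change was 5.79 for Col2a1 (SE 0.27, adjusted p = 7.75e-98) and 5.20 for Acan (SE 0.21, adjusted p = 1.80e-123), higher in 3 of 3 libraries. Without library 1, 2 and 3 these were 6.72, 5.62 and 5.66 for Col2a1 and 5.02, 5.17 and 5.52 for Acan. By the same test without library 1, adjusted p rose to 0.01256 for Col2a1 and 0.02266 for Acan, so the size of the p-values above depends on that library. In all 1425 of 5759 genes changed, 934 higher and 491 lower, and 1150 of 5072 outside the genes used in clustering or naming. The count was 141 without library 1, 776 without library 2 and 1693 without library 3. Inmt (log2 fold change -1.14), Hspg2 (4.23), Hspa5 (2.44), Aldoc (-1.02), Ndufb7 (-0.39), Krt8 (-0.13) and Krt19 (-0.02) lost their calls without library 1, and Aldoc (-0.95), Ndufb7 (-0.97), Krt8 (-0.63) and Krt19 (-0.69) without library 2. Hk2, Tgfb2 and Klf4 were not tested without library 1, and 5, 3 and 1 genes that kept their call moved by more than 1.5 times in fold without library 1, 2 and 3. With DESeq2 size factors 1113 were higher and 406 lower, and the median of all genes moved from 0.05 to 0.16. Library 3 gave 7 cells to the cluster with mitochondrial RNA, fewer than the planned 20. Col2a1 (ENSMUSG00000022483) lies on chromosome 15 from 97975602 to 98004695, Acan (ENSMUSG00000030607) on chromosome 7 from 79053483 to 79115099 and Malat1 (ENSMUSG00000092341) on chromosome 19 from 5795690 to 5802672.

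Camera called 14 lists between the clusters. All 6 cartilage-type matrix genes tested were higher in the cluster with mitochondrial RNA (camera adjusted p = 3.15e-05), as were all 8 basement membrane genes (adjusted p = 3.73e-05), among them the perlecan gene Hspg2 at 204 ± 64.0 against 17.3 ± 21.5 CPM. So were all 4 fibrillar and type VI collagen genes (adjusted p = 3.73e-05), among them Col6a1 at 1020 ± 130 against 70.2 ± 14.3, and all 4 small leucine-rich proteoglycan genes (adjusted p = 0.00398), among them Fmod at 1521 ± 542 against 372 ± 118. Unfolded protein response genes had 12 of 16 higher and 0 lower (adjusted p = 0.00228), with Hspa5 at 343 ± 172 against 78.4 ± 64.8 CPM. Immediate early genes had 15 of 17 higher and 1 lower (adjusted p = 6.32e-04), with Fos at 2311 ± 1965 against 99.4 ± 64.3. Matrix proteases had 6 of 7 higher and 0 lower (adjusted p = 6.32e-04), with Htra1 at 3378 ± 1408 against 667 ± 43.0 CPM, and axon guidance genes 5 of 6 and 0 (adjusted p = 6.32e-04). Osmotic genes had 5 of 8 higher (adjusted p = 0.00792), BMP and TGF-beta genes 7 of 10 (adjusted p = 0.00828), glycosaminoglycan synthesis genes 7 of 12 (adjusted p = 0.00946) and progenitor markers 3 of 3 (adjusted p = 0.00792), each with 0 lower. Nuclear genes of mitochondrial respiration had 7 of 28 lower and 0 higher (adjusted p = 2.25e-04), with Ndufb7 at 225 ± 24.5 against 378 ± 73.0 CPM. Glycolysis genes had 8 of 15 lower and 2 higher (adjusted p = 0.0172), with Aldoc at 60.8 ± 12.96 against 122 ± 24.3 and Hk2 higher at 81.8 ± 21.7 against 21.4 ± 19.8. Adjusted over the list alone, 8 glycosaminoglycan synthesis and 7 protease genes were higher, and 9 glycolysis genes were lower and 3 higher, and the other lists named had the same counts. Each call of this comparison was lost with an estimated correlation, with adjusted p = 0.325 or above with an estimated correlation. Camera so run called 0 lists and had 0 at an unadjusted p under 0.05, and fry called 6. Without library 1, Hspg2 (log2 fold change 4.23), Hspa5 (2.44), Ndufb7 (-0.39) and Aldoc (-1.02) lost their calls.

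Profiles were compared between libraries by the correlation of log2 CPM across genes with a mean of at least 50 CPM, and genes are not independent replicates. For NP-like cells it was 0.829 for libraries 1 and 2, 0.287 for 1 and 3 and 0.344 for 2 and 3 across 2529 genes. For other connective-tissue cells it was 0.834, 0.497 and 0.802 across 2389 genes, and for all other cells 0.836, 0.739 and 0.941 across 2419. The NP-like sum of library 3 held 10859 UMIs, where the smallest connective-tissue sum held 7796372, so counting noise differs between these sums. The mix of the 2 NP-like clusters also differed, with 481 of 483 cells in library 1 and 38 of 138 in library 2 poor in mitochondrial RNA. With Scrublet's threshold the poor cluster gave 1519061 of 2649084 NP-like UMIs in library 1 and 143596 of 1742886 in library 2. The values for NP-like cells therefore do not measure agreement within a single cluster. With Scrublet's threshold, which raised that NP-like sum to 76824 UMIs, the correlations were 0.910, 0.817 and 0.840 for NP-like cells, 0.841, 0.613 and 0.842 for connective-tissue cells and 0.844, 0.774 and 0.952 for all other cells. The median coefficient of variation over the 3 libraries was 54.3%, 19.7% and 16.5% for NP-like, connective-tissue and all other cells, and 24.5%, 18.8% and 16.3% with Scrublet's threshold. No test was made between single libraries.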

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

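All tests in this part were chosen after the result was seen, except the test of damaged cells, whose expected outcome was written before its value was seen. Groups of 3 libraries are too small to test for outlying samples.

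Some barcodes with at least 3 of Krt8, Krt18, Krt19 and T were left out of the comparisons. Those that failed the cell filters numbered 78 in library 1, 5 in library 2 and 10 in library 3. A further 60, 42 and 24 were removed by the preset doublet rate in libraries 1, 2 and 3, where Scrublet's own threshold removed 23, 11 and 0.

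Most NP-like barcodes of libraries 1 and 3, and part of those of library 2, held few mitochondrial and Malat1 UMIs. Shallower sequencing of the same cells was argued against, since at 1000 UMIs each the highest share with a Malat1 UMI in this cluster in libraries 1 and 2 was 21.1%, against 99.2% or more in the other NP-like cluster. S100a8 and S100a9, abundant neutrophil genes, reached 2.55% of their level over all barcodes in library 1 and 0.921% in library 2. These values argue against free RNA in empty droplets with the make-up of all barcodes. The list of barcodes is filtered, so the make-up of free RNA was not measured, and free RNA from NP-like cells stays open. Damage that keeps cytosolic mRNA and loses nuclear and membrane-bound RNA may be the cause: between the clusters, 43 genes of secreted or membrane proteins had a median log2 fold change of 1.26 and 41 genes of cytosolic proteins -0.69, a difference of 1.96 (2-sided permutation test over 100000 permutations, p = 1e-05, the smallest they can give), with ribosomal protein genes at -1.01 and mitochondrially encoded genes at 2.53. The permutation treats genes as independent and holds no spread between libraries, and the clusters were built from the same counts. No biological explanation was tested, and a cell state with the same RNA content stays open.

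The share of NP-like cells differed between libraries by more than counting error. Cell filters and doublet removal were argued against as the whole cause, since among all barcodes the share with at least 3 of the 4 markers was 9.08% (8.44 to 9.76), 1.60% (1.38 to 1.84) and 0.335% (0.236 to 0.462) in libraries 1, 2 and 3, a ratio of 27.1 between highest and lowest, but this ratio was 429 among cells kept with the preset doublet rate and 36.8 with Scrublet's threshold, so doublet removal stays open as part of it. Counting software and annotation were argued against for libraries 2 and 3, which share both and differed by a ratio of 4.76. For unequal carry-over of blood and marrow cells, NP-like cells were set against NP-like and connective-tissue cells together, with Scrublet's threshold. They made up 31.3% (29.2 to 33.5), 19.0% (16.5 to 21.7) and 2.77% (1.83 to 3.9996), a ratio of 11.3. Between libraries 1 and 2 the ratio fell from 6.05 among kept cells to 1.65. These connective-tissue cells included osteoblast-like cells (15, 183 and 595) and bone marrow stromal-like cells (57, 98 and 189), which may be carried over too. Chondrocyte-like cells (1095, 410 and 75) fell in the same order as NP-like cells (561, 169 and 27). The test therefore cannot decide against carry-over as the whole cause, which stays open. Dissection, sorting, pool of animals and, by the labels, sequencing batch differ together between libraries and stay open, as does a difference between animals, and no biological explanation was tested.

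The 6 sums of each comparison have 10 splits into 3 and 3, too few for a share under 0.05, and in each comparison 1 of 10 splits, the real one, gave as many genes. Against all other cells the real split gave 3887 changed genes and the highest other 353, and against other connective-tissue cells 1822 and 646. Against stromal-like cells it gave 1414 and 57, or 0 among the other splits that part the sums of every library, and between the NP-like clusters 1425 and 47. The counts from Scrublet's threshold were 5529 and 0 against all other cells and 3368 and 0 against connective-tissue cells.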

How the results depend on the processing

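The tests with Scrublet's own threshold, with cells chosen by 3 of the 4 markers, with the cluster rich in mitochondrial RNA alone, and all of those between the NP-like clusters were chosen after the result was seen. The cause was not tested for the changes below unless said.

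The mean share of NP-like cells, 3.53%, stayed within 2.72% to 4.44% in 11 settings, less than the SD between libraries, and ranged from 0.724% to 5.28% without each replicate, where the low value is without library 1. The mean is carried by library 1, and the share of library 3, 0.0213%, ran from 0% with a mitochondrial limit of 5% or libraries clustered alone to 0.232% (22 cells) with a limit of 25% and 0.422% (41 cells) with a minimum of 200 genes.

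Against all other cells, 16 of 19 settings gave a count within 1.5 times 3887. The exceptions were a filter of at least 10 CPM in 3 sums, which tests fewer genes (2040), DESeq2 (2361) and equal numbers of cells, which leaves fewer UMIs (1425). Without each replicate the count was 3048 to 4017, and with Scrublet's threshold 4034 to 4860.

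Against other connective-tissue cells, 11 of 19 settings stayed within 1.5 times 1822. The others were the stricter filter (1069), count splitting (1068), DESeq2 (1020), equal cell numbers (1001), no count filter (2787), each library clustered alone, which finds no NP-like cells in library 3 (2863), no doublets removed (3402) and Scrublet's threshold (3368). Count splitting clusters on part of the UMIs and tests on the rest. It thus leaves fewer UMIs and also parts testing from clustering, and these cannot be told apart here. Against all other cells it gave 4299. Without each replicate the count was 1595 to 2248. Under Scrublet's threshold it was 1973 by DESeq2, 2163 with no replicate block and 1765 to 2756 without each replicate.

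Against stromal-like cells, 6 of 14 settings stayed within 1.5 times 1414. The others were at most 5% mitochondrial UMIs (195), DESeq2 size factors (2193), no replicate block (2323), no count filter (2348), 3 of the 4 markers (2478), the cluster with mitochondrial RNA alone (2625), no doublets removed (3150) and Scrublet's threshold (3213), with 413 to 1914 without each replicate. The limit of 5% leaves 0 NP-like cells in library 3, but the preset set without library 3 gave 1914, so fewer libraries alone do not account for 195. With Scrublet's threshold, stromal-like cells had a median of 5.59% mitochondrial UMIs in library 1 and 4.56% in library 2. The limit therefore also removes stromal-like cells, and whether that accounts for 195 was not tested. A minimum of 200 genes, a limit of 25%, libraries clustered alone and resolution 0.4 gave no stromal-like cluster or too few libraries with one, and equal cell numbers were not run here.

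Between the NP-like clusters the count of 1425 was 512 by DESeq2, 653 with no replicate block and 141 to 1693 without each replicate. For the planned sub-clusters, other resolutions, list genes kept in clustering and count splitting were not run, as library 3 had too few cells.

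Camera called 9, 17, 15 and 14 lists in the 4 comparisons in the order above. With an estimated correlation it called 0 in each, and fry called 0, 0, 0 and 6. With Scrublet's threshold camera called 9, 16 and 11 lists in the first 3 comparisons, not all of them the same, and with the cluster with mitochondrial RNA alone 9 against all other, 14 against connective-tissue and 10 against stromal-like cells. Without each replicate the counts were 9 to 10, 13 to 21, 12 to 18 and 11 to 16. The median coefficient of variation between libraries moved from 54.3% to 24.5% with Scrublet's threshold, which gives 27 NP-like cells in library 3 in place of 2.

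For 140 named gene results, 2977 of 3098 values kept direction and side of the threshold, 118 lost the call and 1 gained it. Between the NP-like clusters Krt18, at -0.38 on the log2 scale, ranged from -0.70 to 0.20 without each replicate and T, at -0.27, from -0.58 to 0.12. Both changed sign without library 1, and neither was called before. The NP-like sum of library 3 was the smallest of the NP-like sums with the preset rate, at 10859 UMIs from 2 cells.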

Other observations

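The test of shared barcodes in this part was chosen after the result was seen.

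A cluster of 74 cells in library 1, 3 in library 2 and 2 in library 3 had Calca, Sncg, Prph and Tac1, genes of peripheral neurons, among its leading genes. By Scrublet's threshold 59 of the 74 neuronal-like cells were NP-like. All 623 NP-like cells found with the preset doublet rate were NP-like with that threshold too. A neutrophil lineage-like cluster led by Cxcl2, G0s2, Acod1 and Il1b held 1056 cells in library 1, 78 in library 2 and 30 in library 3. A cluster led by Serpina1b, Cytl1, Cilp2 and Tnmd, named fibroblast-like with the preset doublet rate, held 0, 228 and 88 cells.

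Libraries 2 and 3 shared 224 barcodes, 2.03% of the smaller library, where libraries 1 and 2 shared 24 (0.323%) and libraries 1 and 3 shared 29 (0.390%). In 181 of the 224, 1 library held under 2% of the UMIs of the pair (0 in the other pairs of libraries), with a median of 565 UMIs against 57933. Of the small profiles 62.4% correlated best with the large profile of their own barcode, against 1.10% by chance. Molecules assigned to the other library during sequencing may give this, but the labels state replicate sequencing batches and dual indexing, which would limit such transfer. Whether libraries 2 and 3 shared a run is not given in the sources used here, and the source stays open. The small profile lay in library 2 for 121 and in library 3 for 60, and 6 of them had at least 500 genes. None of the 27 NP-like cells of library 3 found with Scrublet's threshold shared a barcode with library 2.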
